A study of Homo sapiens with 15 samples.

How the data were processed

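Small RNA from DiFi, an established human colorectal cancer cell line, was measured by sequencing. According to the sample records, RNA was purified with the miRNeasy kit and made into libraries with the NEXTflex small RNA kit. The tools listed by the authors are cutadapt 2.10, Bowtie 1.3.1 and FastQC, with the genome build GRCh38. The values are expected counts of reads per mature miRNA as deposited, not normalized, in 1 table of 1619 entries and 14 sample columns. Some values hold fractions, and the rule behind them, the miRNA annotation release and any filters are not stated. Of the 15 samples in the labels, the HDM medium without cells has no column, so it was not analysed here and no medium background could be measured. The labels do not spell out HDM or HF.

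Values were rounded to whole counts, since the count models need them. Of the 14 libraries, 12 belong to 5 groups with replicates: 2 cell pellets, 2 unfiltered HDM samples, 2 filtered HDM samples, and 3 plate cell samples for each of HF6 and HF7. The HDM media and regular media libraries are single. Library totals ran from 205747 to 4896931 counts, so that 3 counts, used as the floor for an entry with no reads, correspond to between 14.6 and 0.613 CPM (counts scaled to a common library total). Intervals and floors cover counting error only, since the reads carry no molecular identifiers in the table. Because the labels do not say whether replicates are separate cultures, p-values measure only the spread between these samples. In the joint fit described next, that spread is estimated over all 5 groups and not only the libraries compared. Plates that differ by plate number therefore enter the p-values of the HDM and pellet comparisons. Each pair of replicates was checked for duplication with a chi-square test of homogeneity. The chi-square per degree of freedom lay between 13.3 and 488, so neither library of a tested pair is a copy of the other.

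The 12 replicated libraries were fitted together with 1 coefficient per group in edgeR 4.0.16 (quasi-likelihood, TMM factors, filterByExpr by group). The filter left 535 miRNAs, which hold 99.96% of the counts. The fit has 7 residual degrees of freedom and a common biological coefficient of variation of 0.363. A miRNA was called at a Benjamini-Hochberg adjusted p under 0.05 within a comparison. Group means of single miRNAs are TMM-normalised CPM with the SD between libraries, and log2 fold changes are given with the standard error of the fit. The 5 comparisons were unfiltered HDM with cell pellets, filtered HDM with cell pellets, filtered with unfiltered HDM, cell pellets with plate cells, and HF7 plates with HF6 plates. Every fold is relative to the other miRNAs of the library, since no spiked-in RNA is in the table.

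Before the data were examined, 23 lists of miRNAs were fixed, and 16 had the 3 or more tested members required. These were the let-7, miR-200, miR-29, miR-30 and miR-15/16 families, the miR-192, miR-194 and miR-215 group, and the miR-17-92, miR-183, miR-96 and miR-182, miR-23/27/24 and miR-221 and miR-222 clusters. The others were the miR-100, miR-125 and miR-99 polycistrons, the miR-320 family with other miRNAs made without Drosha, hypoxia, leukocyte and neural markers, and entries that overlap other RNA classes. The miR-34/449 family, the erythroid, liver, muscle, stromal and endothelial markers and the 14q32 imprinted cluster had too few tested members. Lists were tested with camera from limma 3.58.1 (preset correlation 0.01), adjusted over lists within a comparison. Camera with an estimated correlation and fry were run beside it. A count of members "adjusted over the list alone" uses Benjamini-Hochberg within that list. For the media libraries, the median ratio of a list was ranked among 10000 random lists matched on abundance.

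The miRNAs named were set by a rule fixed before the data were examined. For each comparison it takes the 10 largest increases and the 10 largest decreases among called miRNAs with a mean of at least 100 CPM in 1 group and no overlap between the libraries of the groups. It adds miR-1246, miR-21-5p, miR-210-3p, miR-100-5p, miR-125b-5p, miR-192-5p, miR-200c-3p, let-7a-5p, miR-451a and miR-122-5p, and as list examples the 4 members with the highest mean CPM. For the single libraries it takes the 10 highest CPM, and the 5 highest and 5 lowest ratios among miRNAs with 50 or more counts in the library with the higher CPM. Names outside the rule, and those given for plate numbers, were chosen after their values were seen. Locations were compared with GENCODE release 29, in which 1575 of the 1619 first locations lie within a miRNA gene on the same strand. Of the 1619 entries, 127 differ from another entry by at most 1 mismatch and 133 have more than 1 location.

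Alternatives fixed beforehand were DESeq2 1.42.0, RLE size factors, total counts as the only scaling, no low-count filter, a minimum of 50 counts in at least 2 libraries, limma-voom with quality weights, a fit of only the groups compared, each library left out in turn, and replicate blocks. Leaving out 1 library of a pair keeps a lone sample, which is then assumed to vary like the other groups. Shared numbers were checked as pairs by correlating deviations from the group mean over 281 miRNAs. Between HF6 and HF7 plates of the same number, r was 0.906, 0.823 and 0.742, so plate number served as a block in the comparison of these plates. After the data had been seen, fits without the plate 1 libraries, without the 2 shallowest libraries (205747 and 313398 counts), with plate number as a term, and with plate numbers in place of HF numbers as groups were added.

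The pipeline was tested on simulated data with 200 changed miRNAs in each comparison. Shares are of the changed miRNAs that passed the low-count filter, between 61 and 67 per fold. For true folds of 2, 4 and 8 it recovered 9.84%, 56.1% and 82.8% of changed miRNAs for unfiltered HDM against pellets. The shares were 21.2%, 69.2% and 78.8% for filtered HDM against pellets, and 14.3%, 59.1% and 89.4% for filtered against unfiltered HDM. They were 33.3%, 73.4% and 98.5% for pellets against plates, and 37.5%, 91.0% and 100% for HF7 against HF6 plates. Between 1 and 5 unchanged miRNAs were called per comparison. In 5 draws with no true change, no miRNA was called, 1 list was called with the preset correlation and 0 with an estimated one. The draws took each miRNA on its own, so members of a list were not correlated in them. In the data that correlation was estimated at 0.659 for the let-7 family. The list counts of these draws therefore cannot decide whether the preset correlation is adequate. All simulated libraries were also drawn independently, with 1 spread per miRNA for every group. In the data the plates pair by plate number. The recovered shares and the absence of calls without true change therefore hold only for libraries without such pairing and with a like spread in all groups. Computations used R 4.3.3, Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.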

Results

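Small RNA of DiFi colorectal cancer cells was compared between cell pellets, cells labelled as plates, and HDM samples with or without filtration. The series title names supermeres, a kind of extracellular nanoparticle, and its stated purpose is to try ways of culturing the cells for collecting secreted RNA carriers. The 12 replicated libraries comprise 2 cell pellets, 2 unfiltered HDM samples, 2 filtered HDM samples, 3 HF6 plates and 3 HF7 plates. There was 1 library each of HDM media and regular media. The cell pellets held 3829754 (HF6) and 313398 (HF7) counts, the unfiltered HDM samples 2256525 and 205747, and the filtered HDM samples 2479953 and 1712734. HF6 plates 1, 2 and 3 held 3771619, 4184909 and 1246503 counts, and the HF7 plates 2664161, 3364828 and 3816510. HDM media held 4811447 counts and regular media 4896931.

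miR-21-5p, which is abundant in many carcinomas, had the highest count in all 14 libraries, with between 12.7% and 19.3% of the total. The 10 most abundant miRNAs of each library together held from 52.0% to 57.1%. Over 284 miRNAs with a mean of at least 20 CPM, the first principal component held 59.1% of the variance of log2 CPM and the second 15.4%. The correlation of log2 CPM was 0.950 between the pellets and 0.995 between the plate 1 libraries of HF6 and HF7. Its median was 0.956 between plate 1 and plates 2 and 3, 0.961 between pellets and plate 1, and 0.911 between pellets and plates 2 and 3. For the filtered and unfiltered HDM samples it was 0.897 with pellets, 0.937 with plate 1 and 0.962 with plates 2 and 3. Plates 2 and 3 were thus closer to HDM than to pellets, so HDM against pellets need not stand for HDM against cells in general. These correlations are across miRNAs, which are not independent replicates.

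**Figure D1:**
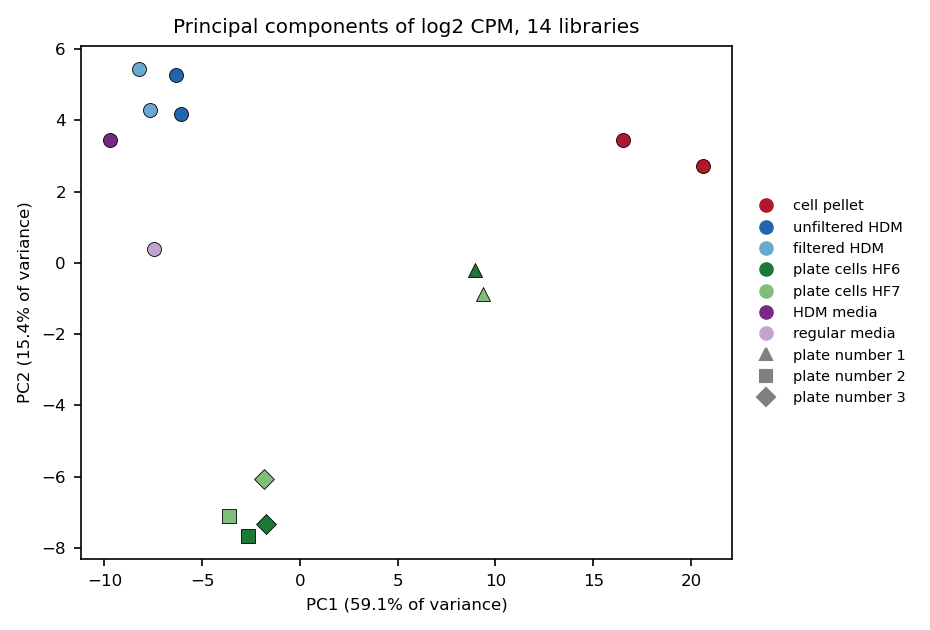
Each point is 1 of 14 libraries placed by the first (59.1% of variance) and second (15.4%) principal components of log2 CPM, coloured by group, with the symbol giving the plate number. The plate 1 libraries of HF6 and HF7, correlated at 0.995, lie together and apart from plates 2 and 3.

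The comparison of unfiltered HDM with cell pellets asks which miRNAs are relatively more or less abundant outside the cells, taking HDM as extracellular, which the labels do not state and no medium background could check. miR-1247-5p was higher in unfiltered HDM by a log2 fold of 4.46 ± 0.49, at 235 ± 97.0 CPM against 11.97 ± 3.59 in pellets (SD, n = 2 each). Its location is chromosome 14, 101560362 to 101560383, in an exon of the lincRNA gene DIO3OS. miR-4521 was 12.8-fold higher, at 566 ± 79.9 CPM against 37.7 ± 43.1, with 188 and 2 counts in the pellets, but plate cells held 615 ± 118 CPM (n = 6). miR-92a-1-5p, the less abundant arm of a hairpin in the MIR17HG host transcript, was 7.20-fold higher. miR-155-5p, from the MIR155HG transcript and known from activated lymphocytes, was 5.36-fold higher. In the other direction, miR-146a-5p, a feedback regulator of innate immune signalling, was 19.98-fold lower, at 290 ± 112 CPM against 5858 ± 1986. miR-210-3p, a target of hypoxia-inducible factors, was 9.37-fold lower, at 167 ± 11.97 CPM against 1570 ± 472. miR-215-5p, an intestinal epithelial miRNA, was 5.92-fold lower, at 400 ± 17.1 CPM against 2368 ± 175.

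edgeR called 59 of 535 miRNAs, 29 higher and 30 lower in unfiltered HDM. Other large increases, as log2 fold with standard error, were miR-29b-1-5p at 2.62 ± 0.46, miR-194-3p at 2.05 ± 0.46, miR-130b-5p at 1.93 ± 0.53 and miR-500a-3p at 1.90 ± 0.46. miR-27b-5p and miR-25-5p stood at 1.68 ± 0.35 and 1.55 ± 0.41. Of the 10 largest increases, 7 were also called lower in pellets than on plates, so they are not all particular to HDM. Both comparisons use the same 2 pellets, so low values in those pellets alone could give both calls. The overlap to expect from that was not computed. Among the decreases were miR-99b-5p at -3.69 ± 1.002, miR-32-5p at -2.55 ± 0.51, miR-126-3p at -2.53 ± 0.61 and miR-338-3p at -2.31 ± 0.69. miR-29c-3p, 1 mismatch from miR-29a-3p, stood at -2.20 ± 0.61, miR-141-3p at -2.14 ± 0.53 and miR-429 at -1.44 ± 0.28. Low values were not particular to HDM for all decreases. miR-210-3p averaged 101 CPM on plate 2 and 287 on plate 3, against 167 in unfiltered HDM, but 726 on plate 1. miR-338-3p averaged 33.9 CPM on plate 2 and 59.7 on plate 3, against 32.6 in unfiltered HDM. miR-146a-5p was higher on plates 2 and 3 than in unfiltered HDM, at 493 and 468 CPM against 290. So was miR-99b-5p, at 83.7 and 37.3 against 22.9. miR-500a-3p lies within 1 mismatch of miR-501-3p and miR-502-3p. The adjusted p of the 10 largest increases ran from 0.000198 to 0.0365 and of the 10 largest decreases from 0.00409 to 0.0468. Of the fixed miRNAs, miR-192-5p was lower at -0.82 ± 0.21 and miR-451a was lower (adjusted p = 0.0279), with 3 and 0 counts in unfiltered HDM against 32 and 2 in pellets. By total-count CPM miR-192-5p differed less, at 42410 and 39960 in unfiltered HDM against 46870 and 49630 in pellets. miR-1246 was not called at -3.48 ± 1.17 (adjusted p = 0.0695), nor were miR-21-5p at -0.66, miR-200c-3p at -0.50, miR-100-5p at -0.61, miR-125b-5p at 0.22 and let-7a-5p at -0.16. miR-122-5p, abundant in liver, had at most 4 counts in any library and was not tested.

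The miR-200 family, which holds epithelial cells in their state by targeting ZEB1 and ZEB2, had 3 of 9 members lower in unfiltered HDM and none higher. Adjusted over the list alone, 5 were lower. miR-200a-3p was lower at -1.14 ± 0.27 and miR-429 as above, while miR-200b-3p was not called at -0.30 ± 0.17. By total-count CPM miR-200b-3p was higher in unfiltered HDM, at 68460 and 78580 against 55660 and 64230 in pellets. miR-200a-3p and miR-429 stayed lower by that measure. Camera gave adjusted p = 0.0238. With an estimated correlation the adjusted p = 0.589, the highest of 11 camera alternatives, whose lowest was 0.0185. In the miR-192, miR-194 and miR-215 group, typical of gut epithelium, 3 of 6 members were lower and 1 was higher, and adjusted over the list alone 4 were lower and 1 higher. miR-194-5p was lower at -1.28 ± 0.23, while the other arm, miR-194-3p, was higher. Camera gave adjusted p = 0.0356 for this group. Its adjusted p = 0.589 with an estimated correlation, the top of a range from 0.0280. In the miR-30 family 2 of 8 members were lower, miR-30e-5p at -1.19 ± 0.31 and miR-30b-5p at -1.19 ± 0.33, and adjusted over the list alone 3 were. miR-30d-5p and miR-30c-5p stood at -0.64 and -0.56. The camera adjusted p of the family was 0.0249. Estimating the correlation gave adjusted p = 0.589, the top of a range from 0.0151.

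Leukocyte markers went both ways: miR-146a-5p was lower, miR-155-5p was higher, and miR-150-5p, named after its values were seen, was higher at 5.33 ± 0.90, with 128 and 15 counts in unfiltered HDM against 4 and 0 in pellets. Adjusted over the list alone, 2 of the 5 were higher and 2 lower, and camera gave adjusted p = 0.999. The remaining 12 lists had camera adjusted p from 0.0835 to 0.912. The median, mean and camera direction differed in sign for the leukocyte, miR-29 and miR-320 lists.

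Libraries of the groups did not overlap for 275 of 535 miRNAs (51.4%), where chance gives 33.3%. The call count fell to 34 without the HF6 pellet, to 7 without the HF6 unfiltered sample and to 15 without the HF7 unfiltered sample. Scaling by total counts alone, which moves the median log2 fold of all miRNAs from 0.05 to 0.66, gave 68 higher and 12 lower. limma-voom gave 19 and 36. Calls rose from 59 to 149 without the plate 1 libraries and to 160 with plate number as a term. With total counts as the only scaling the medians of the 3 called lists stayed negative, with camera adjusted p of 0.0807, 0.0752 and 0.0807.

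**Figure D2:**
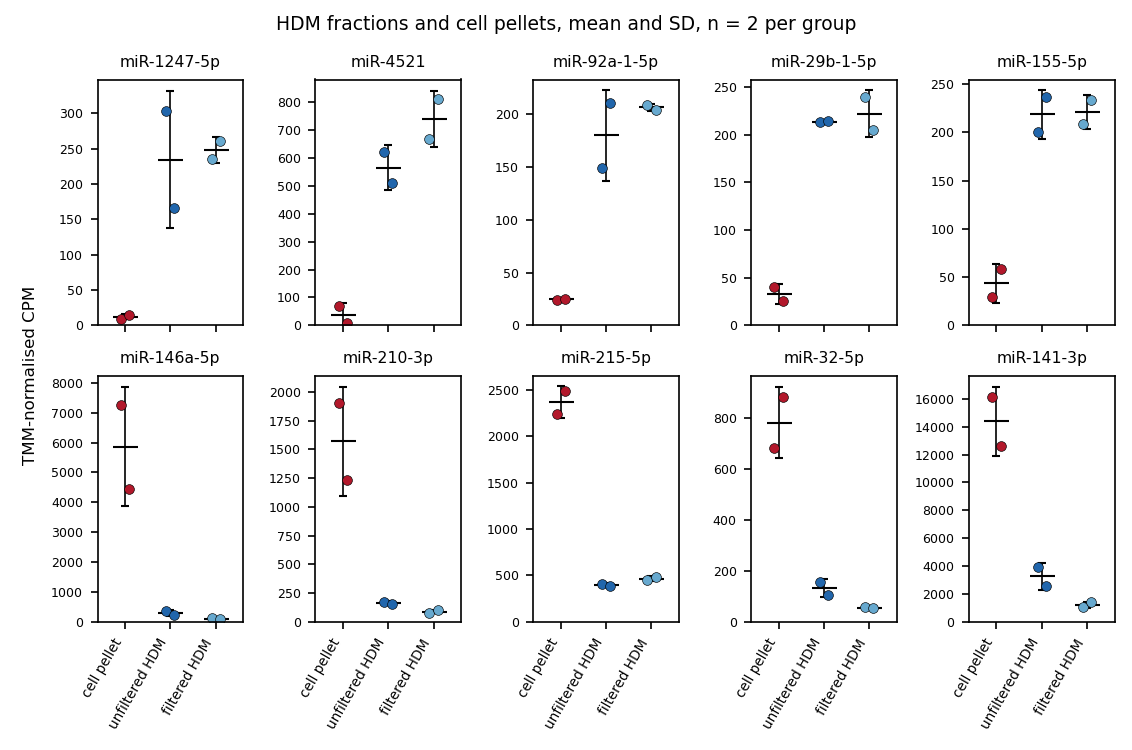
TMM-normalised CPM (linear axes) of 10 miRNAs in each of the 2 libraries of cell pellets, unfiltered HDM and filtered HDM, with the mean and SD as lines that end at 0. miR-1247-5p averaged 11.97 CPM in pellets and 235 in unfiltered HDM, and miR-146a-5p 5858 and 290.

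The comparison of filtered HDM with the same pellets puts the question after filtration. miR-1247-5p was 22.9-fold higher in filtered HDM, at 248 ± 18.2 CPM (n = 2), and miR-4521 was 16.7-fold higher, at 740 ± 99.3. miR-552-3p was 4.18-fold higher, at 168 ± 19.8 CPM against 40.1 ± 0.273. miR-146a-5p was 57.0-fold lower, at 103 ± 12.2 CPM against 5858 ± 1986. miR-210-3p was 17.7-fold lower, at 88.8 ± 16.3 CPM. miR-32-5p, from an intron of TMEM245, was 14.1-fold lower, at 55.3 ± 4.12 CPM against 782 ± 140. miR-141-3p, a miR-200 family member, was 11.9-fold lower, at 1213 ± 240 CPM against 14376 ± 2474.

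edgeR called 97 miRNAs, 47 higher and 50 lower in filtered HDM. The log2 folds of other large increases were 3.06 ± 0.48 for miR-92a-1-5p, 2.68 ± 0.46 for miR-29b-1-5p, 2.57 ± 0.53 for miR-130b-5p and 2.45 ± 0.67 for miR-155-5p. They were 2.20 ± 0.46 for miR-194-3p, 2.09 ± 0.47 for miR-500a-3p and 2.08 ± 0.51 for miR-12135. Here too 7 of the 10 largest increases were called lower in pellets than on plates, again with the same pellets in both comparisons. Decreases comprised miR-12136 at -4.03 ± 0.79, miR-99b-5p at -3.47 ± 0.95, miR-126-3p at -3.30 ± 0.61, miR-338-3p at -2.61 ± 0.68, miR-3609 at -2.58 ± 0.81 and miR-29c-3p at -2.40 ± 0.60. miR-12136 and miR-3609 differed widely between the pellets, at 22932 ± 24251 and 408 ± 433 CPM. Plate 2 was again low for miR-210-3p, at 101 CPM against 88.8 in filtered HDM, and for miR-338-3p, at 33.9 against 28.6. For miR-146a-5p plate 2 stayed higher, at 493 CPM against 103. The adjusted p of these increases ran from 0.000165 to 0.0220 and of the decreases from 0.00176 to 0.0407. miR-451a was lower at -2.53 ± 0.67. miR-1246 was not called at -3.28 ± 1.16 (adjusted p = 0.0638), nor miR-192-5p at -0.58, miR-21-5p at -0.55, miR-100-5p at -1.95, miR-125b-5p at 0.54, let-7a-5p at 0.26 and miR-200c-3p at -0.49.

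The miR-200 family had 4 of 9 members lower in filtered HDM, and 5 adjusted over the list alone. miR-429 was lower at -1.196 ± 0.28 and miR-200a-3p at -0.997 ± 0.27, while miR-200b-3p stood at -0.07. By total-count CPM miR-200b-3p was higher in filtered HDM, at 77090 and 78110 against 55660 and 64230 in pellets. Camera gave adjusted p = 0.0140 for the family. With an estimated correlation the adjusted p = 0.576, the top of a range from 0.00882. The miR-30 family had 2 of 8 lower, miR-30e-5p at -1.70 ± 0.31 among them, and adjusted over the list alone 6 were lower. Its camera adjusted p was 0.00309. Estimating the correlation gave adjusted p = 0.576, the top of a range from 0.00204. The miR-192, miR-194 and miR-215 group had 3 of 6 lower and miR-194-3p higher, and adjusted over the list alone 4 lower and 1 higher. miR-194-5p stood at -1.37 ± 0.23 and miR-215-5p at -2.35 ± 0.42. Camera gave adjusted p = 0.0454 for the group. It was adjusted p = 0.576 with an estimated correlation, the top of a range from 0.0211.

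Other lists were not called by camera. Of the miR-183, miR-96 and miR-182 cluster, expressed in sensory cells and many carcinomas, 3 of 6 members were lower (list alone 3, camera adjusted p = 0.324). They were miR-182-5p at -1.48 ± 0.38, miR-183-5p at -1.204 ± 0.39 and miR-96-5p at -2.11 ± 0.48. In the miR-23/27/24 clusters 3 of 11 were higher and 1 lower (list alone 4 and 2, camera adjusted p = 0.458). Of the miR-17-92 cluster and paralogs 2 of 17 were higher (list alone 1), with camera adjusted p = 0.149. In the miR-29 family 1 of 7 was higher and 2 lower, the same counts as adjusted over the list alone (camera adjusted p = 0.665). miR-16-5p alone was lower in the miR-15/16 family (list alone 2, camera adjusted p = 0.149), and miR-99b-5p alone in the miR-100, miR-125 and miR-99 polycistrons (list alone 3, camera adjusted p = 0.164). Among hypoxia markers miR-210-3p was the 1 of 9 called, also adjusted over the list alone, with camera adjusted p = 0.351. miR-484 was the 1 of 7 higher in the miR-320 list (list alone 2, camera adjusted p = 0.404). miR-338-3p was the 1 of 5 neural markers called, also adjusted over the list alone (camera adjusted p = 0.324). Entries overlapping other RNA classes had 1 of 23 higher and 2 lower (list alone 6 and 5, camera adjusted p = 0.455). None of 9 let-7 members or 4 members of the miR-221 and miR-222 cluster was called in either count, with camera adjusted p of 0.455 and 0.792. Leukocyte markers again went both ways, with miR-150-5p (5.42 ± 0.89, from 187 and 81 counts against 4 and 0) and miR-155-5p higher and miR-146a-5p and miR-142-5p (-2.25 ± 0.39) lower. Adjusted over that list alone, 2 were higher and 3 lower, and camera gave adjusted p = 0.455.

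Groups did not overlap for 335 miRNAs (62.6%, with 33.3% from chance). Without the HF6 filtered sample 11 miRNAs were called, and without the HF7 filtered sample 32. Total counts as the only scaling moved the median of all miRNAs from 0.09 to 0.59 and gave 94 higher and 37 lower. The camera adjusted p of the 3 called lists was then 0.0450, 0.0450 and 0.00838, with medians still negative. Calls rose from 97 to 179 without the plate 1 libraries and to 205 with plate number as a term.

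**Figure D3:**
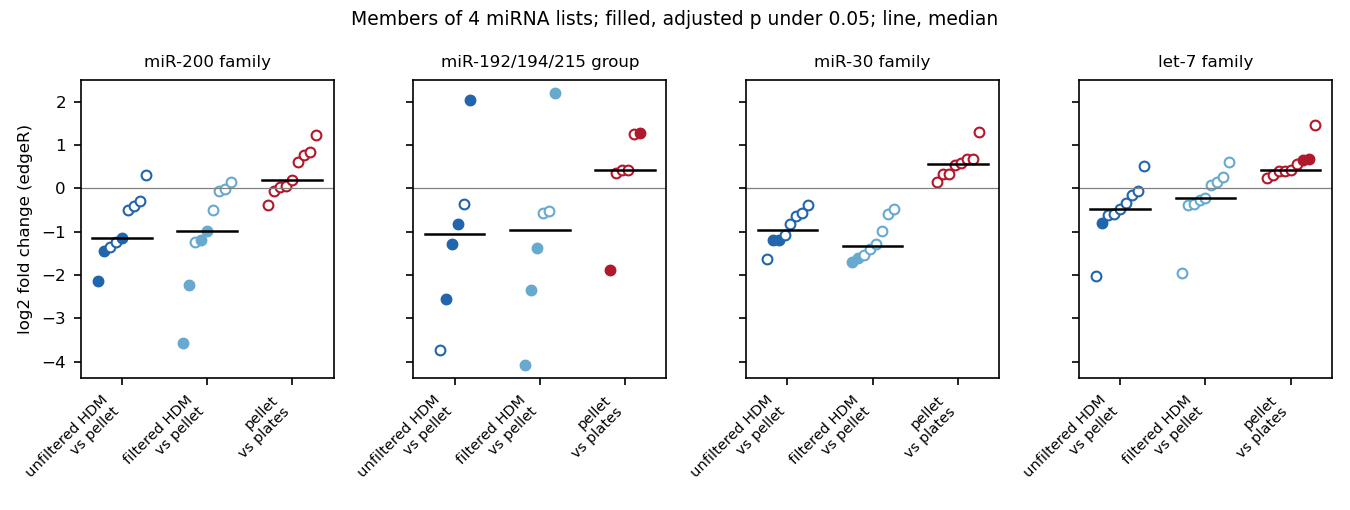
Log2 fold changes of each tested member of the miR-200 family, miR-192, miR-194 and miR-215 group, miR-30 family and let-7 family in 3 comparisons, filled where the adjusted p was under 0.05, with the list median as a line. In filtered HDM against pellets the miR-30 median was -1.34, or -0.89 when total counts were the only scaling. In pellets against plates the let-7 median was 0.41, or 0.09 under that scaling.

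Filtered and unfiltered HDM were compared to ask what filtration changes, and no miRNA passed the test in edgeR. The largest of the fixed miRNAs by abundance, miR-21-5p, averaged 134604 ± 25334 CPM in filtered and 124834 ± 21352 CPM in unfiltered HDM (n = 2 each), a log2 fold of 0.11 ± 0.26. let-7a-5p stood at 0.41 ± 0.25, miR-192-5p at 0.24 ± 0.20, miR-125b-5p at 0.33 ± 0.32 and miR-200c-3p at 0.01 ± 0.52. miR-1246 stood at 0.19 ± 1.07, miR-210-3p at -0.92 ± 0.86, and the scarce miR-100-5p and miR-451a at -1.35 ± 0.86 and 0.71 ± 0.93. All of these had adjusted p = 0.999.

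Unadjusted p was under 0.05 for 10 miRNAs in edgeR, and the calls numbered 0 in DESeq2, 1 in limma-voom and 3 in edgeR without the low-count filter. A fit of only these 4 libraries called 14 miRNAs, 13 lower and 1 higher in filtered HDM. They comprised miR-12136 at -1.73 ± 0.19, miR-146a-5p at -1.62 ± 0.20, miR-141-3p at -1.49 ± 0.19 and miR-32-5p at -1.36 ± 0.19, with miR-4497 higher at 1.82 ± 0.37, all named after their values were seen. The fixed miR-210-3p was also among those lower, at -0.97 ± 0.19 (edgeR adjusted p = 0.0161). Its standard error was 0.86 in the fit of all groups. Libraries did not overlap for 210 miRNAs (39.3%, with 33.3% from chance). Leukocyte markers were lower as a list (camera adjusted p = 0.0154), although 0 of 5 members was called, also when adjusted over the list alone. With an estimated correlation the adjusted p = 0.187, within a range over 11 camera alternatives from 0.000199 to 0.538. miR-146a-5p, miR-142-3p and miR-142-5p stood at -1.51 ± 0.91, -0.69 ± 0.37 and -1.04 ± 0.38, and miR-155-5p at 0.02 ± 0.60. The other 15 lists had camera adjusted p from 0.0603 to 0.977, with 0 members called in either count. Median, mean and camera direction differed in sign for the miR-200, miR-183, miR-96 and miR-182, miR-221 and miR-222, miR-100, miR-125 and miR-99, hypoxia, neural and other RNA class lists.

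Cell pellets and plate cells are both cellular, and their comparison asks how far these collections differ. miR-1246, an entry that overlaps U2 small nuclear RNA sequence and has been described in extracellular RNA, was 6.93-fold higher in pellets, at 5721 ± 3090 CPM (n = 2) against 859 ± 1037 on plates (n = 6). Its location is chromosome 2, 176601024 to 176601042. miR-146a-5p was 4.82-fold higher, at 5858 ± 1986 CPM against 1226 ± 1183. miR-182-5p was 2.57-fold higher, at 13490 ± 1067 CPM against 5253 ± 1872. let-7f-5p was 1.59-fold higher, at 45849 ± 211 CPM against 28875 ± 3396, and lies 1 mismatch from let-7a-5p. In the other direction miR-4521 was 13.9-fold lower in pellets, with 615 ± 118 CPM on plates. miR-12135, from an intron of NEO1, was 6.93-fold lower, at 224 ± 160 CPM against 1508 ± 417.

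edgeR called 44 miRNAs, 23 higher and 21 lower in pellets. Further increases were miR-29c-3p at 1.58 ± 0.44, miR-215-5p at 1.28 ± 0.31, miR-181d-5p at 1.25 ± 0.35, miR-148a-3p at 0.97 ± 0.27, miR-26a-5p at 0.91 ± 0.25 and let-7g-5p at 0.66 ± 0.18. Decreases comprised miR-92a-1-5p at -2.42 ± 0.43, miR-194-3p at -1.89 ± 0.41, miR-4485-3p at -1.84 ± 0.37, miR-130b-5p at -1.68 ± 0.46, miR-29b-1-5p at -1.60 ± 0.40 and miR-27b-5p at -1.14 ± 0.30. Adjusted p ran from 0.0172 to 0.0475 for the increases and from 0.00601 to 0.0432 for the decreases. The fit takes no account of plate number, and with plate number as a term the calls numbered 165, with 90 higher and 75 lower. miR-210-3p was not called at 2.09 ± 0.62 (adjusted p = 0.0544) but was with plate number as a term (adjusted p = 2.09e-05). That term takes the difference between plate numbers out of the spread, so p-values with it do not cover that difference. The log2 fold of miR-210-3p was 1.07 against plate 1 only and 2.98 against plates 2 and 3 only. Also not called were miR-451a at 1.204, miR-192-5p at 0.35, let-7a-5p at 0.41, miR-200c-3p at 0.83, miR-100-5p at 1.23, miR-21-5p at 0.31 and miR-125b-5p at -0.30.

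let-7, a family that restrains growth and was among the earliest known miRNAs, had 2 of 9 members higher in pellets, let-7f-5p and let-7g-5p, in both counts, overall and adjusted over the list alone. let-7b-5p stood at 0.39 ± 0.25. Camera gave adjusted p = 0.00428. With an estimated correlation the adjusted p = 0.643, the top of a range over 17 camera alternatives from 0.00101. The miR-30 family was higher as a list (camera adjusted p = 0.0347) with 0 of 8 members called in either count. Estimating the correlation gave adjusted p = 0.643, the top of a range from 0.0228. Against plate 1 only the let-7 and miR-30 lists had camera adjusted p of 0.0810 and 0.227, and against plates 2 and 3 only 0.0109 and 0.0513. fry, a test against no change and not against other miRNAs, gave adjusted p of 0.125 and 0.0912. Entries overlapping other RNA classes went both ways, with 6 of 23 higher and 3 lower, and 7 and 7 adjusted over the list alone (camera adjusted p = 0.664). miR-1246 and miR-12136 (2.74 ± 0.52) were among those higher and miR-4485-3p among those lower. The other 13 lists had camera adjusted p from 0.189 to 0.730. For leukocyte markers the median was negative, and the mean and camera direction positive.

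Libraries did not overlap for 168 miRNAs (31.4%). Chance gives 7.14% for exchangeable libraries, which the plates are not, since they pair by plate number. Total counts as the only scaling moved the median of all miRNAs from -0.08 to -0.45 and gave 15 higher and 65 lower, and limma-voom gave 44 and 16. Under that scaling the let-7 and miR-30 lists had camera adjusted p of 0.0738 and 0.133. A fit of only the pellets and plates called 0. Calls numbered 113 without HF6 plate 1 and 121 without HF7 plate 1. They numbered 12 and 18 without HF6 plates 2 and 3, and 20 and 16 without HF7 plates 2 and 3.

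**Figure D4:**
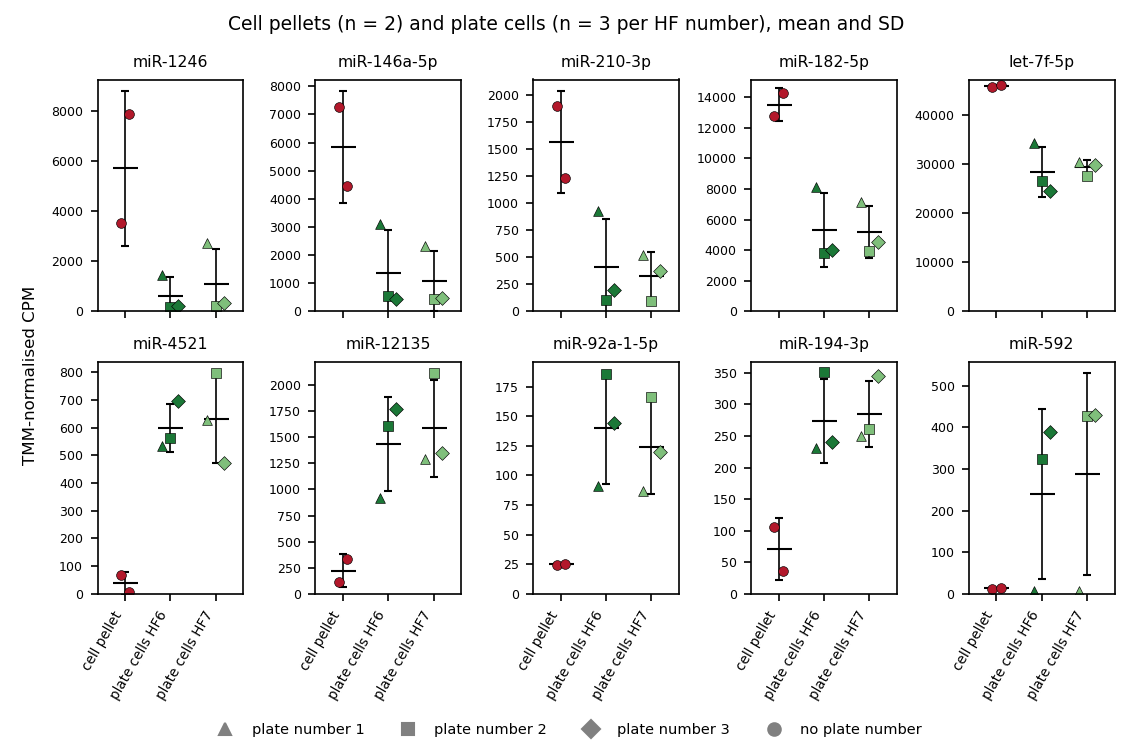
TMM-normalised CPM (linear axes) of 10 miRNAs in 2 cell pellets and 3 plates for each HF number, with the plate number as symbol and the mean and SD as lines that end at 0. miR-592 averaged 7.62 CPM on plate 1, 377 on plate 2 and 409 on plate 3.

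The libraries of plate number 1 stood apart, so plate numbers were compared in a fit with HF6 and HF7 together, a comparison added after the data had been seen. hsa-miR-592, from an intron of GRM8 (chromosome 7, 127058148 to 127058169), averaged 7.62 ± 0.25 CPM on plate 1, 377 ± 72.6 on plate 2 and 409 ± 28.3 on plate 3 (n = 2 each). It averaged 13.1 ± 2.05 CPM in pellets, 168 ± 12.8 in unfiltered HDM and 216 ± 10.01 in filtered HDM. miR-375-3p, known from endocrine cells, averaged 4028 ± 414 CPM on plate 1, 465 ± 35.7 on plate 2 and 1054 ± 347 on plate 3. miR-1246 averaged 2095 ± 879, 209 ± 35.8 and 272 ± 100 CPM, and miR-146a-5p 2717 ± 569, 493 ± 69.2 and 468 ± 13.6. miR-125a-5p averaged 506 ± 103, 127 ± 34.3 and 45.8 ± 13.1 CPM, and miR-210-3p 726 ± 282, 101 ± 9.05 and 287 ± 121.

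The edgeR test of any difference between plate numbers called 113 of 535 miRNAs, and plate 1 had the highest or lowest mean for 107 of them. Since each miRNA has 1 highest and 1 lowest plate, plates 2 and 3 were at an end for 63 and 56. Plate 1 against plate 2 gave 67 higher and 58 lower, plate 1 against plate 3 gave 53 higher and 40 lower, and plate 2 against plate 3 gave 0 higher and 1 lower. Pellets differed from plate 1 in 31 miRNAs, from plate 2 in 208 and from plate 3 in 172. The first count is not comparable with that of the fit against plate 1 only, given below. There the HF6 and HF7 plate 1 libraries are separate groups of 1 library each. The count over plate numbers was 43 without either plate 1 library and 65 without HF7 plate 2. In the comparison of pellets with plate cells, 187 miRNAs were called when the plate 1 libraries were left out. Unfiltered and filtered HDM against pellets then gave 149 and 179.

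Plate cells of HF7 and HF6 were compared to ask how far the 2 HF numbers differ, and no miRNA passed the test in edgeR. miR-21-5p averaged 157347 ± 46576 CPM on HF7 and 161920 ± 28389 on HF6 plates (n = 3 each), a log2 fold of -0.04 ± 0.22. miR-192-5p stood at -0.04 ± 0.17, let-7a-5p at -0.04 ± 0.20, miR-125b-5p at 0.05 ± 0.26 and miR-200c-3p at -0.15 ± 0.43. miR-1246 stood at 0.82 ± 0.87, miR-210-3p at -0.32 ± 0.68, miR-451a at -0.43 ± 0.47 and miR-100-5p at -0.06 ± 0.61. Each had adjusted p = 0.999. Unadjusted p was under 0.05 for 7 miRNAs in edgeR, and DESeq2 and limma-voom called 0. With plate number as a block in the 6 plate libraries, 4 were called. These were miR-4485-3p at 0.80 ± 0.16, miR-4284 at 0.83 ± 0.19 and miR-1246 at 0.69 ± 0.17, all higher on HF7 plates, and miR-3613-5p at -0.67 ± 0.18. miR-4284 and miR-3613-5p were named after their values were seen.

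Entries overlapping other RNA classes were higher on HF7 plates as a list (camera adjusted p = 0.0405), with 0 of 23 members called in either count. With an estimated correlation the adjusted p = 0.199. Over 13 camera alternatives it ran from 0.00442, with plate number as a block, to 0.296. In the blocked fit an estimated correlation gave adjusted p = 0.965, and fry gave 0.994 without the block and 0.708 with it. The other 15 lists had camera adjusted p from 0.164 to 0.977, and 0 members were called. Median, mean and camera direction differed in sign for the let-7, miR-200 and miR-183, miR-96 and miR-182 lists. Libraries of HF6 and HF7 did not overlap for 25 miRNAs (4.67%). Chance gives 10% for exchangeable plates, which these are not, given the pairing by plate number.

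HDM media and regular media were sequenced as 1 library each, so their difference has no replicates and no test. The labels do not say whether they hold medium conditioned by cells. Their correlation of log2 CPM with the HDM samples had a median of 0.983, and whether the values below are medium background or secreted RNA is unknown. In both, miR-21-5p, miR-194-5p, miR-200b-3p, miR-192-5p, miR-92a-3p, miR-29a-3p, miR-7-5p, miR-200c-3p, miR-200a-3p and let-7f-5p were the 10 most abundant. miR-21-5p held 146489 CPM in HDM media (exact 95% interval 146148 to 146832) and 163739 CPM in regular media (163381 to 164098). miR-150-5p, a lymphocyte miRNA, had 93.5 CPM in HDM media and 35.3 in regular media, a ratio of 2.65 (2.22 to 3.17). Its total-count CPM was 61.3 ± 19.9 in filtered HDM, 64.8 ± 11.4 in unfiltered HDM and 0.522 ± 0.739 in pellets (n = 2 each). The other high ratios were 3.38 (2.37 to 4.91) for miR-3679-5p, 2.69 (2.23 to 3.26) for miR-10401-3p, 2.69 (1.81 to 4.06) for miR-664b-3p and 2.62 (1.55 to 4.56) for miR-590-5p. Low ratios were 0.426 (0.403 to 0.450) for miR-4485-3p, 0.426 (0.271 to 0.657) for miR-10525-3p, 0.527 (0.391 to 0.706) for miR-4485-5p, 0.528 (0.375 to 0.735) for miR-126-3p and 0.548 (0.523 to 0.574) for miR-374a-3p. Among fixed miRNAs the ratio was 1.40 (1.28 to 1.54) for miR-1246 and 1.52 (1.348 to 1.71) for miR-210-3p. It was 0.979 for miR-192-5p, 0.895 for let-7a-5p and 0.966 for miR-125b-5p. miR-200c-3p had 31990 CPM in HDM media and 24607 in regular media, while miR-100-5p, miR-451a and miR-122-5p had at most 15 counts.

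Of 357 miRNAs with 50 or more counts, 27 had at least 2-fold more CPM in HDM media and 2 had at least 2-fold less, around a median log2 ratio of 0.24. Scaled by TMM, these counts were 13 and 5. The median log2 ratio of leukocyte markers was 0.71, at percentile 99.47 of 10000 random lists of like abundance, and that of the miR-320 list was 0.68, at percentile 99.26. The miR-100, miR-125 and miR-99 polycistrons had a median of -0.24, at percentile 0.57. The other 13 lists lay between percentiles 3.97 and 96.83.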

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

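The fits that leave out the plate 1 libraries or the 2 shallow libraries, use plate number as a term or limit the plates by number, the crossed pairing, and all values of the test over plate numbers were chosen after the data had been seen; the other alternatives were planned. Of 81 named values that had been called, DESeq2 kept 79, RLE size factors 81, limma-voom 79, no low-count filter 72, total counts only 61 and the HF number block 80. None of them changed direction in any alternative. Many of them had been chosen for large folds without overlap in these same data, which makes a change of direction unlikely. Values not called did change direction. In the fits that kept all 366 named values, these numbered from 5 with plate number as a term to 62 with total counts only. With plate number as a term 42 named values not called before were called. With only the groups compared 57 of 80 kept their call, without the 2 shallow libraries 32 of 81, against plate 1 only 1 of 19, while 206 of 400 lost it when 1 library was left out. For the changed counts given here the cause was not tested.

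For pellets against plates, DESeq2 gave 74 calls, total counts only 80, no low-count filter 111, and a fit of only these groups 0. The numbers were 1 against plate 1 only and 187 against plates 2 and 3 only. For filtered against unfiltered HDM, no low-count filter gave 3, limma-voom 1, only the groups compared 14 and plate number as a term 1. Plate number as a block gave 4 for HF7 against HF6 plates. Without the plate 1 libraries unfiltered HDM, filtered HDM and plates against pellets gave 149, 179 and 187, and with plate number as a term 160, 205 and 165. Without the 2 shallow libraries unfiltered HDM against pellets gave 7 and pellets against plates 22. Leaving out 1 library gave 7 to 48 calls for unfiltered HDM against pellets, 11 to 92 for filtered HDM against pellets, 12 to 121 for pellets against plates, and 0 throughout for both comparisons without calls. For the test over plate numbers this range was 43 to 87, and DESeq2 gave 114, with 96 of the 113 miRNAs among them.

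The HF number is shared by samples, but deviations of libraries with the same number correlated at only 0.04, 0.19 and -0.21. As a block it gave 69, 112, 0 and 46 calls in the comparisons other than HF7 with HF6 plates. Crossing that number in the filtered HDM libraries gave 0. Camera called 10 lists over the 5 comparisons, against 6 with total counts only, 0 with an estimated correlation and 4 without the 2 shallow libraries. Of 50 list calls 26 were lost when 1 library was left out. fry called 10 lists, 6 of them among those called by camera. For the media libraries, a minimum of 10 counts gave 104 ratios of at least 2-fold in either direction and TMM scaling 18, in place of 29. Depth limits the HF7 pellet and the HF7 unfiltered sample most, where 3 counts correspond to 9.57 and 14.6 CPM.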

Other observations

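The tests of plate number, its technical explanations and the interaction with HF number were chosen after the data had been seen, while the hairpin arm and filtration tests and the splits of the plate libraries were set before their results were seen. hsa-miR-99b-5p, hsa-let-7e-5p and hsa-miR-125a-5p lie together on chromosome 19 within an intron of SPACA6, from 51692618 to 51693291, and among plate numbers each had its highest mean on plate 1, a group named after its values were seen. miR-99b-5p averaged 276 ± 55.1 CPM on plate 1, 83.7 ± 15.4 on plate 2 and 37.3 ± 1.07 on plate 3 (n = 2 each), let-7e-5p 95.5 ± 11.5, 41.8 ± 0.144 and 24.5 ± 1.98, and miR-125a-5p is given with the plates. In unfiltered HDM against pellets, miR-99b-5p was lower, while let-7e-5p at -2.02 ± 0.76 and miR-125a-5p at -2.73 ± 1.09 were not called.

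Further miRNAs called over plate numbers in edgeR comprised miR-27a-3p and miR-23a-3p, which share a hairpin cluster. miR-27a-3p averaged 10335 ± 1985 CPM on plate 1, 2645 ± 315 on plate 2 and 2911 ± 110 on plate 3, and miR-23a-3p 12030 ± 339, 4601 ± 145 and 4959 ± 111. miR-135b-5p, often raised in colorectal tumours, averaged 1957 ± 104, 390 ± 100 and 538 ± 225 CPM, and miR-625-3p 316 ± 49.9, 90.2 ± 11.9 and 77.4 ± 1.58. In the other direction, miR-501-5p averaged 51.1 ± 0.268, 174 ± 25.7 and 127 ± 15.8 CPM, and miR-500a-5p, from the same region of chromosome X, 131 ± 15.3, 391 ± 33.5 and 334 ± 29.7.

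Plate 1 libraries of both HF numbers differed from plates 2 and 3, with 113 miRNAs called over plate numbers: thinning all plate libraries to 1246503 counts left 95 calls, and removing each library's trend on GC content and length gave 155, which argues against depth and against GC content or length as the whole cause. A mixture of pellet RNA into plate 1 cannot be told apart. Its share was computed for miRNAs called at 2-fold or more between pellets and the base plate, with a mean of at least 100 CPM in either. These were 64 miRNAs with plate 2 as base and 50 with plate 3. The median share was 0.758 for HF6 and 0.669 for HF7 with plate 2 as base, and 0.744 and 0.646 with plate 3. Of these miRNAs 28.1% and 32% lay over 0.2 from the median in both libraries. With each pellet alone as the endpoint only 9.38% and 16% did so on the same side, and exchanging the pellets moved the shares of 51.6% and 44% by over 0.2, so the difference between 2 pellets keeps the mixture open, in a test revised 2 times after its values had been seen. Shares outside 0 to 1 in both libraries, which a mixture does not give, were found for 10.9% and 10% of miRNAs, counted with no tolerance. Among them hsa-miR-592 passed 1 only narrowly, from means of 7.62 CPM on plate 1 and 13.1 CPM in pellets. hsa-miR-193b-3p passed it narrowly in HF7. Further above 1, and against a mixture, stood hsa-miR-135b-5p, hsa-miR-125a-5p and hsa-miR-181a-5p (2.38 and 1.98 with plate 2 as base). These and hsa-miR-592 were over 0.2 from the median with each pellet alone. The 2-fold limit left out hsa-miR-23a-3p, whose values also go against a mixture. Its total-count CPM on plate 1 was 10500 (HF6) and 11220 (HF7), against 7461 and 6209 in pellets. Plates 2 and 3 held 4908 and 4991 for HF6, and 4680 and 5144 for HF7. All are single miRNAs picked after their values were seen, and the percentage over all miRNAs with a share stayed under the bound for excluding a mixture. A library batch or a difference in culture between plate numbers may also remain, and no biological explanation was tested, since the labels give none.

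Minor arms of hairpins may be relatively higher in unfiltered HDM than in pellets. Over 164 hairpins, the log2 fold change of the less abundant arm minus that of the other had a median of 0.47 (108 of 164 above 0, sign-flip permutation p = 0.00029, adjusted over 6 tests 0.00174). Some minor arms, such as miR-34a-3p at a mean log2 CPM of 1.89, lay under the floor of 14.6 CPM of the HF7 unfiltered sample. Some major arms entered repeatedly, such as miR-24-3p for both miR-24-1 and miR-24-2. With the GC trend removed the difference was 0.31 (permutation p = 0.00309), which argues against GC content as the whole cause. With the abundance trend removed it was 0.03 (permutation p = 0.774), so abundance stays open. In HDM against plate cells it was 0.096 (permutation p = 0.300), in filtered HDM against pellets 0.17 (permutation p = 0.106) and in pellets against plates -0.25 (permutation p = 0.00212), so a property of the pellets alone also stays open. Arms of different hairpins are not independent replicates, and no biological explanation beyond the hypothesis was tested.

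Filtration may lower RNA that resembles the pellets. Across 183 miRNAs with at least 100 CPM, the log2 ratio of filtered over unfiltered HF6 HDM correlated with that of pellet over unfiltered HF7 HDM at Spearman's rho = -0.40 and Pearson's r = -0.40 (permutation p = 1e-05, the smallest the permutations can give). With the HF numbers exchanged, rho was -0.25 and r -0.35 (permutation p = 0.00077), these being the 2 pairings computed, with no library in common within either. The weaker rho was -0.223 with the GC trend removed and -0.306 with the abundance trend removed, which argues against both as the whole cause. miRNAs are not independent replicates, the edgeR test called 0 of them, and other effects of filtration were not tested.

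Among the 10 ways to split the 6 plate libraries into 3 and 3, all 10 gave at least the 0 calls of HF7 against HF6, and the highest other gave 10, so a share under 0.05 is impossible in this design. The 4 splits with both plate 1 libraries on 1 side gave 2, 10, 0 and 4 calls, where the third library was HF6 plate 2, HF6 plate 3, HF7 plate 2 and HF7 plate 3, and the count with plate number as a block was 4. A test of whether 4 comparisons differ by HF number, with 4 residual degrees of freedom from the plates, called 0 miRNAs in edgeR. Each pellet and HDM sample in it is alone, and the spread comes from plates that differ by plate number, so the 0 calls say little about HF number. Unadjusted p was under 0.05 for 36, 51, 7 and 57 miRNAs, and no other tool was run.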
